A study of Mus musculus with 60 samples.

How the data were processed

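The samples were 60 RNA-seq libraries from the mPFC of DBA2/J mice that express GFP-L10a, a ribosomal protein with a fluorescent tag. Per the labels' protocols, tissue was frozen, tagged ribosomes were pulled down with an antibody against GFP for the IP samples, and RNA was extracted with the Direct-zol kit. Libraries were made with the SMART-Seq v4 kit and the TruSeq v2 kit and read on a NovaSeq instrument as pairs of 100 bases, per the labels' protocols. The labels do not state a strand setting. SMART-Seq amplifies complementary DNA, and without molecular identifiers the reads are not independent molecules, so every interval and floor given covers counting error only.

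The authors deposited 1 table of expected counts, which are estimated read or fragment counts per gene that need not be whole, for 55414 genes and 60 libraries. That unit was read from the values: 88.4% were whole within 0.000001 and the columns summed to different totals. The submitters' processing notes name Trimmomatic 0.32, TopHat2 2.0.13, Bowtie2 2.2.3 and the build mm10, with no role or order. The counting tool, its treatment of reads that match several genes and its strand setting are not given in the sources used here. Gene positions in the deposited table are not those of mm10. In all 38981 genes were matched by gene symbol to a gene table of GRCm38, the assembly behind mm10. Of these 0.747% had the same start, and starts differed by 136604 bases at the median. Positions are therefore printed as the table gives them, and no reference sequence was used with them.

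Each column was matched to its sample by name and each sample to its group by its label, and 0 value columns were left unmatched. Expected counts were rounded to whole numbers before the count tests. In all 19770 genes had 0 counts in every library. Library totals were 19078928 to 27073456 counts. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 16670 genes in the IP fit, 18170 in the Input fit and 18937 in the fit of both. The common biological coefficient of variation was 23.7% in IP, 18.6% in Input and 22.2% in both, and for genes with counts in the top 25% it was 8.11%, 7.28% and 8.02% at the median. These spreads set the precision of a fold change for genes with many counts, and counting error adds to it for genes with few.

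Tests were edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and Benjamini-Hochberg adjustment at 0.05. The 30 libraries of a fraction were fitted together with 5 groups, and each subtype was set against NS in IP and in Input, while pairs of subtypes were compared in IP. A fit of all 60 libraries with 10 groups gave IP against Input, as the mean over the 5 groups, and the test of whether the differences from NS were unlike in the fractions. CPM were computed from the counts with the TMM factors of the same fit, and log CPM used a prior count of 2. In all 29 gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and members were also adjusted within their list alone. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and ratios against groups with few counts have exact 95% intervals.

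The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took from IP against Input and from each comparison with NS the 10 largest rises and the 10 largest falls among genes that passed and reached a mean of 10 CPM in the higher group, predicted genes left out. It added up to 4 members with the smallest p from each list described, and Rpl10a, Fos, Fkbp5 and Bdnf in every comparison. Comparisons between subtypes, the tests of any difference and the test between fractions gave their 5 smallest adjusted p. Of the genes the rule allowed, those with the plainest background are described, and some are not reported here.

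Alternatives fixed in advance were edgeR with RLE factors, DESeq2 1.42.0, limma voom with library quality weights, no filter on low counts, fits of only the 12 libraries compared, the replicate number as a block, and for lists an estimated correlation, fry and the block. Added after the data were seen were leaving out processed pseudogenes, leaving out named libraries, RES as the reference in Input, and an oligodendrocyte covariate in IP. In the fit of both fractions the replicate block paired the IP and Input libraries of equal group and number. With 6 libraries per group, single libraries were not left out in turn. Libraries of a group were compared pairwise for repeats, and none differed by as little as sampling noise, so all 60 were counted.

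The count tests were tested on simulated data with the means and library sizes of the real libraries, 50 genes changed at each of 4 fold sizes. The changed genes were drawn from those with a mean of at least 20 counts per library. Recovery of genes with fewer counts was therefore not measured. For SA against NS in IP, over 16670 genes, edgeR recovered 18% of changed genes at 1.2-fold, 76% at 1.5-fold, 76% at 2-fold and 88% at 4-fold, with 10 false calls among 139. For SA against NS in Input, over 18170 genes, it recovered 26%, 60%, 82% and 100%, with 5 false calls among 139, and for IP against Input, over 18937 genes, 64%, 84%, 98% and 100%, with 18 among 191. For the test of any difference in IP it recovered 12%, 78%, 74% and 92%, with 5 false calls among 133. DESeq2 in the first of these comparisons made 32 false calls among 170, and limma 6 among 130. In that comparison camera called 0 of 20 unchanged lists and called the raised list.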

Results

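RNA was sequenced from the medial prefrontal cortex (mPFC) of DBA2/J mice, an inbred strain, in which ribosomal protein L10a carried a GFP tag. Pulling the tagged ribosomes down with an anti-GFP antibody (IP) gives RNA bound by ribosomes of the cells that carry the tag. The labels describe these IP samples as neurons of the mPFC projecting to the aPVT, and the paired kind of sample (Input) as bulk mPFC taken with no antibody. The series describes 5 days of social defeat, in which a mouse is repeatedly attacked by an aggressor, and the labels do not say which of the groups went through it. The labels put the samples into 4 subtypes named SA, SA:ANH, ANH and RES and a further group named NS, and do not spell these names out. Each of the 10 combinations of group and fraction held 6 libraries, 60 in all. Library totals lay between 19078928 counts in ANH IP replicate 6 and 27073456 in SA Input replicate 3. Mitochondrially encoded genes took 0.0289% of the counts in IP and 1.76% in Input. Nothing in the labels says that the 6 libraries of a group came from separate animals, so all p-values measure only the spread between these libraries, which may be technical. Log2 fold changes are given ± SE, and levels as mean ± SD in CPM (counts scaled to a common library total), with n = 30 per fraction or n = 6 per group. Adjusted p-values of genes are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The members of a gene list are those tested in that comparison, and a list's median is that of their log2 fold changes. Calls of the camera gene set test printed without a second p also held when the correlation between genes was estimated. Gene positions are those of the deposited table, whose genome build is not given in the sources used here.

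To find which transcripts the pulldown enriched, the 30 IP libraries were compared with the 30 Input libraries. Most glutamate and GABA receptor genes, ion channel genes and layer 5 markers stood higher in IP, and markers of glia, blood vessels, immune cells and interneurons stood far lower. Rpl10a, the tagged protein, was higher in IP (log2 fold change 2.28 ± 0.03, adjusted p = 3.29e-59; 406 ± 51.7 against 83.6 ± 10.2 CPM; ENSMUSG00000037805.16, chromosome 17, 28547445 to 28550007). Its processed pseudogene copy Rpl10a-ps1 rose by 3.35 ± 0.02, and reads of the gene, of the tagged transgene and of this copy cannot be told apart. Among the largest rises was Ap3b2, a neuronal subunit of the AP-3 vesicle coat (3.28 ± 0.02, adjusted p = 5.28e-76; 2180 ± 717 against 212 ± 12.1 CPM; ENSMUSG00000062444.16, chromosome 7, 81110147 to 81143673). Clasp2, a microtubule plus-end protein, rose by 2.66 ± 0.03, Inhba, a subunit of activin, by 2.09 ± 0.07, and Scyl2 by 2.30 ± 0.08. Bdnf, a neurotrophin, rose by 1.95 ± 0.03, from 19.9 ± 2.8 to 76.8 ± 9.97 CPM, and Fkbp5, a glucocorticoid-induced chaperone, by 0.22 ± 0.05 (adjusted p = 0.000179), while Fos, an immediate early gene, stood at -0.29 ± 0.05 (adjusted p = 6.77e-07).

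Among the genes lowest in IP were a neuronal noncoding RNA, mitochondrial transcripts and markers of other cell types. Lrrc17 stood at -7.53 ± 0.13, the noncoding RNA Bc1 of neurons at -7.15 ± 0.11 (1.22 ± 0.564 against 166 ± 46.5 CPM) and the mitochondrially encoded mt-Rnr2 and mt-Co3 at -7.15 ± 0.07 and -7.13 ± 0.06. The smooth muscle actin Acta2 stood at -6.89 ± 0.25, and the microglial or macrophage genes Lyz2, Tyrobp, Itgam and P2ry13 at -6.87 ± 0.23, -6.75 ± 0.17, -6.62 ± 0.26 and -6.58 ± 0.26. For microglia and macrophage markers, 0 of 20 members rose, 20 fell and 0 did not pass, with equal counts adjusted over the list alone (median -5.68; camera adjusted p = 9.84e-12). All 20 astrocyte markers, all 20 endothelial and mural markers and all 20 oligodendrocyte markers fell, with equal counts adjusted over the list alone (medians -3.88, -4.79 and -3.2; camera adjusted p = 3.34e-16, 1.35e-09 and 3.26e-13). The myelin gene Mbp fell by 3.08 on the log2 scale (SE 0.02) and was still at 307 ± 197 CPM in IP, against 2160 ± 421 CPM in Input. For markers of inhibitory neurons, of 20 members 1 rose, 19 fell and 0 did not pass, with equal counts adjusted over the list alone (median -3.73; camera adjusted p = 4.48e-11). The interneuron peptide Sst stood at -3.75 ± 0.02 and the calcium buffer Pvalb at -3.96 ± 0.05. The mitochondrially encoded genes all fell, at a median of -5.16 over 15 members, equally adjusted over the list alone (camera adjusted p = 9.24e-16).

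Among projection neuron classes, markers of layer 5 extratelencephalic neurons, the deep-layer cells that project below the cortex, were higher in IP. There 13 of 16 members rose, 2 fell and 1 did not pass, with equal counts adjusted over the list alone (median 0.67; camera adjusted p = 1.99e-06), with Bcl11b, a transcription factor of these cells, at 1.44 ± 0.03. Markers of layer 6 corticothalamic neurons went the other way. There 2 of 17 members rose, 14 fell and 1 did not pass, with equal counts adjusted over the list alone (median -1.55; camera adjusted p = 8.13e-05), with Cplx3 at -4.41 ± 0.10 and Rprm at -2.12 ± 0.04. Of the general excitatory markers, of 15 members 13 rose, 2 fell and 0 did not pass, with equal counts adjusted over the list alone (median 0.59; camera adjusted p = 9.5e-06). Ionotropic glutamate receptors and their scaffolds rose as a group: of 42 members 31 rose, 5 fell and 6 did not pass, with equal counts adjusted over the list alone (median 0.51; camera adjusted p = 4.25e-09). Gria2 stood at 1.53 ± 0.02 and Grin2b at 2.07 ± 0.03. For voltage-gated ion channels, 32 of 42 members rose, 8 fell and 2 did not pass, with equal counts adjusted over the list alone (median 0.53; camera adjusted p = 2.91e-09), with the sodium channel Scn2a at 1.47 ± 0.02. For GABA receptors, of 16 members 14 rose, 2 fell and 0 did not pass, with equal counts adjusted over the list alone (median 0.61; camera adjusted p = 5.03e-07). Gabra2 stood at 1.5 ± 0.03. Monoamine and acetylcholine receptors did not rise as a group: of 33 members 11 rose, 14 fell and 8 did not pass, with equal counts adjusted over the list alone (median -0.13; camera adjusted p = 0.662). Htr3a stood at -4.67 ± 0.21 and Chrna4 at -1.11 ± 0.06. Over all genes, 14280 of 18937 differed, 6218 higher and 8062 lower in IP, of which 1046 and 3589 differed at least 2-fold.

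**Figure D1:**
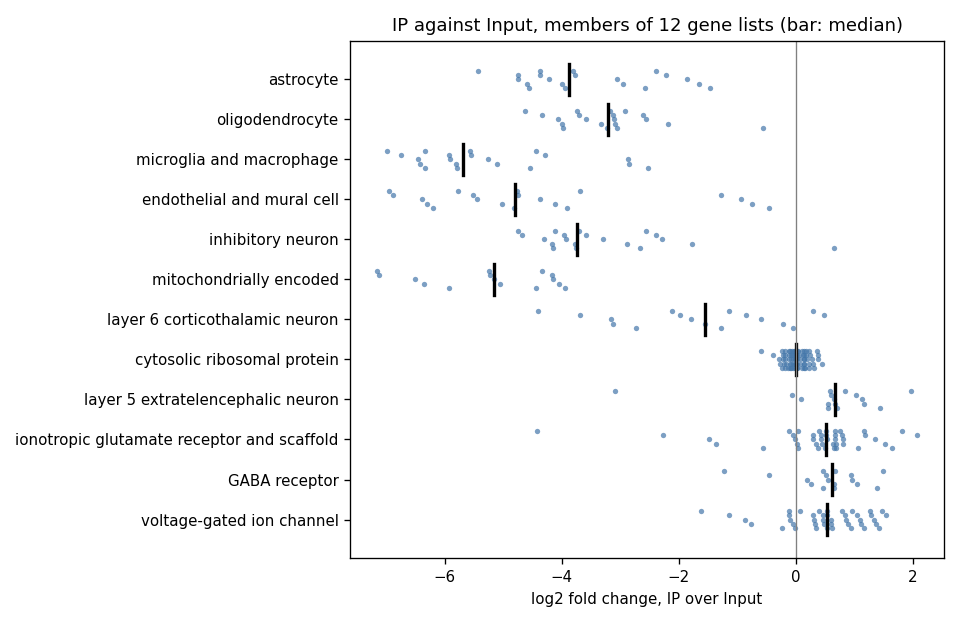
Log2 fold change between IP and Input (horizontal axis) of each measured member of 12 gene lists (rows); each point is a gene, and each vertical bar is the list's median, from 30 libraries per fraction. Lists of glial, vascular, immune and inhibitory neuron markers lie left of 0 (medians -3.88 for astrocytes and -5.68 for microglia), and the glutamate receptor, GABA receptor, channel and layer 5 lists lie mostly right of 0.

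The 4 subtypes were then compared with NS within the IP fraction, to ask which transcripts in the pulldown differed from that group. Whether a given transcript in IP was bound to tagged ribosomes was not tested. In SA, nuclear-retained long noncoding RNAs, ribosomal protein genes and genes of oxidative phosphorylation were higher than in NS, and immediate early genes were lower. Malat1, a long noncoding RNA kept in the nucleus, stood at 929 ± 152 CPM against 237 ± 14.3 in NS (1.97 ± 0.12, adjusted p = 1.76e-14; ENSMUSG00000092341.4, chromosome 19, 5845718 to 5852700). Meg3, an imprinted noncoding RNA, rose by 1.5 ± 0.05, Snhg11 by 1.71 ± 0.06, Miat by 1.59 ± 0.16 and Kcnq1ot1, a noncoding antisense transcript within Kcnq1, by 1.79 ± 0.20. The library kit does not mark strand as far as the labels state, so reads of Kcnq1ot1 and of its host gene cannot be told apart. For Malat1, Meg3 and Snhg11 all 6 SA libraries lay above all 6 NS libraries. Of the noncoding RNA list, of 11 members 7 rose, 2 fell and 2 did not pass, with equal counts adjusted over the list alone (median 1.5; camera adjusted p = 2.12e-09). The same libraries held more mitochondrially encoded RNA, 0.0432% ± 0.00555 of counts against 0.0202% ± 0.00247 in NS IP: of 15 members 13 rose, 0 fell and 2 did not pass, with equal counts adjusted over the list alone (median 1.08; camera adjusted p = 2.52e-14). Red cell transcripts moved with them, as Hba-a1 rose by 1.24 ± 0.12 to 22 ± 2.65 CPM and Hbb-bs by 1.37 ± 0.16.

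For the cytosolic ribosomal proteins in SA IP, 73 of 74 members rose, 0 fell and 1 did not pass, with equal counts adjusted over the list alone (median 0.58; camera adjusted p = 6.49e-75). Rps27 rose by 1.02 ± 0.07, Rps23 by 0.82 ± 0.06 and Rpl13 by 0.68 ± 0.06. Of 846 processed pseudogenes tested in this comparison, 22 were higher and 83 lower. Such copies share reads with their parent genes. What this adds to the rise of the list was not tested, since pseudogenes were left out only in Input. For nuclear-encoded oxidative phosphorylation genes, of 74 members 61 rose, 0 fell and 13 did not pass, and 64 rose and 1 fell adjusted over the list alone (median 0.28; camera adjusted p = 1.39e-26). Cdkn1c, a cell cycle inhibitor, rose by 1.52 ± 0.11. The falls were led by Il16 (-2.91 ± 0.26), Trf, the transferrin gene expressed by oligodendrocytes (-2.26 ± 0.25), Lats2, a Hippo pathway kinase (-2.12 ± 0.25), Rasd1 (-2.09 ± 0.20), the serotonin receptor Htr7 (-1.98 ± 0.25) and the transcription factor Zbtb20 (-1.92 ± 0.13). Among the activity-regulated immediate early genes, of 27 members 0 rose, 13 fell and 14 did not pass, with equal counts adjusted over the list alone (median -0.34; camera adjusted p = 3.26e-07). Egr1 stood at -0.80 ± 0.05, adjusted p = 6.22e-14 (ENSMUSG00000038418.8, chromosome 18, 34992876 to 34998037), Nr4a2 at -1.56 ± 0.17 and Bdnf at -0.39 ± 0.06, adjusted p = 1.2e-05 (68.5 ± 3.04 against 89.7 ± 6.41 CPM). Fkbp5 fell by 0.63 on the log2 scale (SE 0.14, adjusted p = 0.00129). Fos (-0.23 ± 0.11, adjusted p = 0.177) and Rpl10a (0.03 ± 0.05, adjusted p = 0.785) did not pass.

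Excitatory neuron markers fell in SA IP: of 15 members 2 rose, 8 fell and 5 did not pass, and 2 rose and 9 fell adjusted over the list alone (median -0.22; camera adjusted p = 6.67e-06). The pentraxin Nptx1 stood at -0.75 ± 0.05 and the kinase Camk2a at -0.57 ± 0.05. Oligodendrocyte markers fell as well: of 20 members 0 rose, 8 fell and 12 did not pass, and 0 rose and 9 fell adjusted over the list alone (median -0.53; camera adjusted p = 5.14e-05). Mbp stood at -0.22 ± 0.05. For astrocyte markers, of 19 members 1 rose, 8 fell and 10 did not pass, and 1 rose and 9 fell adjusted over the list alone (median -0.40; camera adjusted p = 9.84e-05). Gfap stood at -2.29 ± 0.35. The peptides Sst and Penk stood at -0.91 ± 0.08 and -1.09 ± 0.08. Layer 5 extratelencephalic markers went both ways: of 15 members 5 rose, 3 fell and 7 did not pass, and 5 rose and 4 fell adjusted over the list alone (median 0.16; camera adjusted p = 0.351). Fezf2 rose by 0.48 ± 0.05, Pou3f1 by 0.32 ± 0.06 and Parm1 by 0.29 ± 0.06, and Bcl11b stood at -0.29 ± 0.07. For glutamate receptors and scaffolds, of 42 members 2 rose, 15 fell and 25 did not pass, and 3 rose and 17 fell adjusted over the list alone (median -0.12; camera adjusted p = 0.00144). In all, 2766 of 16670 genes differed between SA and NS IP, 1566 higher and 1200 lower.

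In SA:ANH IP, ribosomal protein genes were higher than in NS and markers of layer 5 extratelencephalic neurons lower. Every measured ribosomal protein gene rose: of 74 members 74 rose, 0 fell and 0 did not pass, with equal counts adjusted over the list alone (median 0.67; camera adjusted p = 1.2e-78), led by Rps27 at 1.15 ± 0.07, adjusted p = 3.53e-14 (104 ± 14.6 against 46.9 ± 3.01 CPM; ENSMUSG00000090733.7, chromosome 3, 90119829 to 90120958). For the layer 5 list, 0 of 15 members rose, 14 fell and 1 did not pass, with equal counts adjusted over the list alone (median -0.68; camera adjusted p = 1.91e-18). Bcl11b stood at -1.13 ± 0.07, adjusted p = 2.54e-14 (ENSMUSG00000048251.16, chromosome 12, 107876662 to 107969861), the neurofilament Nefm at -0.77 ± 0.06 and Parm1 at -0.73 ± 0.06. For layer 6 corticothalamic markers, of 16 members 0 rose, 6 fell and 10 did not pass, and 0 rose and 7 fell adjusted over the list alone (median -0.50; camera adjusted p = 0.000363). The peptide Cck rose by 0.75 ± 0.04, the calcium buffer Calb1 by 0.77 ± 0.07 and Sst by 0.45 ± 0.07. The largest rises were those of the hemoglobins Hbb-bs (1.40 ± 0.16) and Hba-a1 (1.38 ± 0.12), of Trbc2 (1.35 ± 0.08), of the troponin Tnnc1 (1.35 ± 0.11) and of the neuronal transcription factor Pou3f2 (1.24 ± 0.19). The largest falls were Zfp536 (-2.24 ± 0.29), Il16 (-2.14 ± 0.25) and Filip1 (-1.98 ± 0.32).

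Of the immediate early genes in SA:ANH IP, of 27 members 1 rose, 12 fell and 14 did not pass, with equal counts adjusted over the list alone (median -0.28; camera adjusted p = 1.37e-07). Egr1 stood at -0.71 ± 0.05, Vgf, a secreted neuropeptide precursor, at -0.69 ± 0.06, Fos at -0.72 ± 0.11, adjusted p = 9.58e-06, and Bdnf at -0.19 ± 0.06, adjusted p = 0.0213. Fkbp5 fell by 0.72 on the log2 scale (SE 0.14, adjusted p = 0.000179) and Rpl10a rose by 0.22 ± 0.05 (adjusted p = 0.00193). Oxidative phosphorylation genes were mostly higher: of 74 members 62 rose, 4 fell and 8 did not pass, with equal counts adjusted over the list alone (median 0.34; camera adjusted p = 9.98e-27, and adjusted p = 0.0826 with an estimated correlation). For the noncoding RNAs, of 11 members 6 rose, 1 fell and 4 did not pass, and 7 rose and 1 fell adjusted over the list alone (median 0.55; camera adjusted p = 0.00212, and adjusted p = 0.0555 with an estimated correlation). Malat1 stood at 1.08 ± 0.12. The mitochondrially encoded share was 0.0302% ± 0.00862, and for those genes of 15 members 11 rose, 0 fell and 4 did not pass, with equal counts adjusted over the list alone (median 0.54; camera adjusted p = 6.32e-05, and adjusted p = 0.213 with an estimated correlation). Of the oligodendrocyte markers, of 20 members 1 rose, 9 fell and 10 did not pass, with equal counts adjusted over the list alone (median -0.76; camera adjusted p = 5.13e-05). Mbp stood at -0.79 ± 0.05, adjusted p = 1.7e-13. Between SA:ANH and NS IP 3288 of 16670 genes differed, 1879 higher and 1409 lower.

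In ANH IP, myelin transcripts stood higher than in NS. Mbp, a structural protein of myelin, was at 430 ± 8.15 CPM against 194 ± 12.8 (1.15 ± 0.05, adjusted p = 7.28e-18; ENSMUSG00000041607.18, chromosome 18, 82493271 to 82603762), and all 6 ANH libraries lay above all 6 NS libraries. Trf rose by 1.94 ± 0.21, Mobp by 1.62 ± 0.12, Mag by 1.54 ± 0.23 and Car2, a carbonic anhydrase of oligodendrocytes, by 1.64 ± 0.14. For the oligodendrocyte list, 14 of 20 members rose, 0 fell and 6 did not pass, and 16 rose and 0 fell adjusted over the list alone (median 1.51; camera adjusted p = 2.51e-25). For astrocyte markers, of 19 members 3 rose, 0 fell and 16 did not pass, and 4 rose and 1 fell adjusted over the list alone (median 0.10; camera adjusted p = 0.207). Gfap rose by 1.33 ± 0.31. Inhibitory neuron markers moved with the myelin genes: of 19 members 3 rose, 0 fell and 16 did not pass, and 3 rose and 1 fell adjusted over the list alone (median 0.39; camera adjusted p = 0.0114). Sst stood at 1.03 ± 0.07, adjusted p = 2.52e-12 (ENSMUSG00000004366.5, chromosome 16, 23708323 to 23709708) and the peptide Npy at 1.07 ± 0.09. Layer 5 extratelencephalic markers fell: of 15 members 0 rose, 11 fell and 4 did not pass, with equal counts adjusted over the list alone (median -0.38; camera adjusted p = 3.78e-15). Bcl11b stood at -0.74 ± 0.07 and Nefm at -0.64 ± 0.06. Ap3b2 and Clasp2, among the most enriched in IP, stood at -0.90 ± 0.04, adjusted p = 2.5e-18 (1110 ± 51.9 against 2070 ± 77.9 CPM) and -0.90 ± 0.04.

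Other large falls in ANH IP were Filip1 (-1.75 ± 0.32) and Il16 (-1.54 ± 0.24). The dopamine signalling protein Ppp1r1b stood at -0.83 ± 0.06. For oxidative phosphorylation genes, of 74 members 0 rose, 27 fell and 47 did not pass, and 0 rose and 54 fell adjusted over the list alone (median -0.14; camera adjusted p = 9.76e-19, and adjusted p = 0.147 with an estimated correlation). For chaperones, of 27 members 0 rose, 7 fell and 20 did not pass, and 0 rose and 9 fell adjusted over the list alone (median -0.11; camera adjusted p = 0.000414). Of the ribosomal protein genes, of 74 members 0 rose, 1 fell and 73 did not pass, and 0 rose and 0 fell adjusted over the list alone (median -0.04; camera adjusted p = 0.0857). Bdnf fell by 0.25 on the log2 scale (SE 0.06, adjusted p = 0.00723) and Fkbp5 by 0.46 (SE 0.14, adjusted p = 0.035), while Fos (0.03 ± 0.11, adjusted p = 0.931) and Rpl10a (-0.01 ± 0.05, adjusted p = 0.972) did not pass. Of 16670 genes, 1233 differed between ANH and NS IP, 504 higher and 729 lower.

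RES IP held the highest mean level of Mbp of the 5 IP groups. It was at 610 ± 37.6 CPM against 194 ± 12.8 in NS (1.66 ± 0.05, adjusted p = 1.56e-22), with all 6 RES libraries above all 6 NS libraries. Opalin, Trf, Bcas1, Mog, Mal and Mag rose by between 2.56 and 2.86 on the log2 scale. For oligodendrocyte markers, 16 of 20 members rose, 0 fell and 4 did not pass, and 18 rose and 0 fell adjusted over the list alone (median 2.05; camera adjusted p = 9.18e-44), and for their precursors, of 12 members 3 rose, 0 fell and 9 did not pass, with equal counts adjusted over the list alone (median 0.91; camera adjusted p = 0.000252). As in ANH, Sst rose, here by 1.49 ± 0.07, adjusted p = 8.93e-17, and Npy by 0.58 ± 0.09. Of the inhibitory neuron markers, of 19 members 2 rose, 0 fell and 17 did not pass, with equal counts adjusted over the list alone (median 0.45; camera adjusted p = 5.9e-05). Among the largest falls were immediate early genes, Npas4 at -1.32 ± 0.19, Fosl2 at -0.92 ± 0.18, Nr4a2 at -0.90 ± 0.17 and Btg2 at -0.79 ± 0.12. Egr1 fell by less, at -0.64 ± 0.05, adjusted p = 4.07e-11. Of the immediate early list, of 27 members 2 rose, 9 fell and 16 did not pass, and 3 rose and 15 fell adjusted over the list alone (median -0.23; camera adjusted p = 1.03e-09). Bdnf stood at -0.43 ± 0.06, adjusted p = 1.24e-05 and Fos at -0.45 ± 0.11, adjusted p = 0.0152.

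Ribosomal protein genes were higher in RES IP: of 74 members 37 rose, 0 fell and 37 did not pass, and 70 rose and 0 fell adjusted over the list alone (median 0.23; camera adjusted p = 1.04e-38). Rpl10a rose by 0.39 ± 0.05, adjusted p = 5.22e-06, and Fkbp5 did not pass (-0.15 ± 0.14, adjusted p = 0.695). Several red cell, noncoding and mitochondrially encoded transcripts were also higher in RES IP. Hba-a1 rose by 0.64 ± 0.12, adjusted p = 0.000634, and Hbb-bs by 0.73 ± 0.16. For the noncoding RNA list, of 11 members 4 rose, 1 fell and 6 did not pass, and 5 rose and 1 fell adjusted over the list alone (median 0.09; camera adjusted p = 0.00143). Malat1 rose by 0.42 ± 0.12, adjusted p = 0.0282, Meg3 by 0.44 ± 0.05 and Snhg11 by 0.51 ± 0.06. For the mitochondrially encoded genes, of 15 members 2 rose, 0 fell and 13 did not pass, and 7 rose and 0 fell adjusted over the list alone (median 0.39; camera adjusted p = 3.03e-06, and adjusted p = 0.116 with an estimated correlation). Among them mt-Rnr2 rose by 0.65 ± 0.14. For the astrocyte markers, of 19 members 3 rose, 0 fell and 16 did not pass, and 4 rose and 1 fell adjusted over the list alone (median 0.18; camera adjusted p = 0.178). Gfap rose by 1.45 ± 0.31, adjusted p = 0.00381. For layer 5 extratelencephalic markers, of 15 members 0 rose, 4 fell and 11 did not pass, and 0 rose and 5 fell adjusted over the list alone (median -0.17; camera adjusted p = 9.31e-06). For voltage-gated ion channels, of 42 members 0 rose, 7 fell and 35 did not pass, with equal counts adjusted over the list alone (median -0.10; camera adjusted p = 6.15e-05). RES had the fewest differences from NS IP, 727 of 16670 genes, 375 higher and 352 lower. With each library's mean level of the oligodendrocyte list as a covariate, chosen after the data were seen, 609 genes passed in SA, 815 in SA:ANH, 9 in ANH and 2 in RES. Differences between groups held 98.3% of the variance of that covariate.

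**Figure D2:**
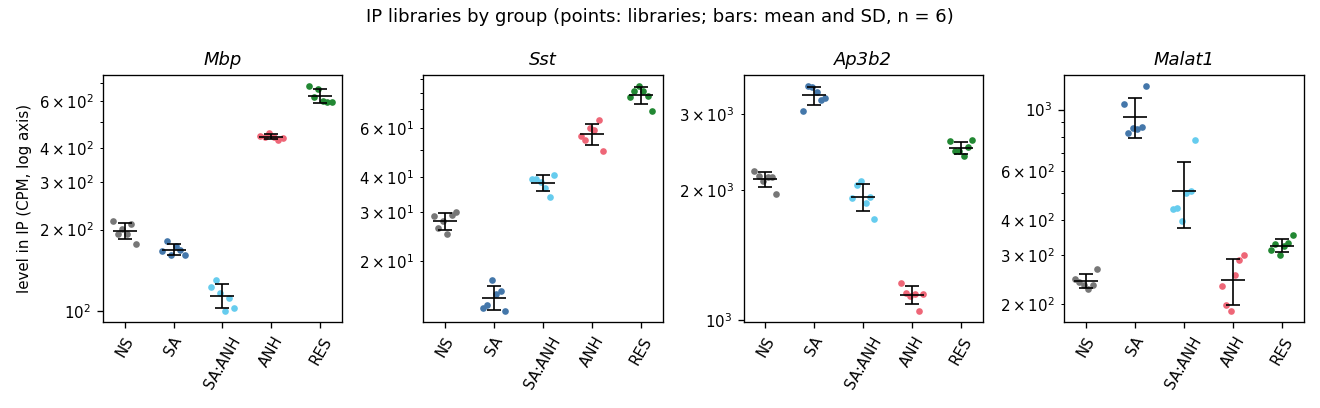
Levels of Mbp, Sst, Ap3b2 and Malat1 in the 30 IP libraries, in CPM scaled over all 60 libraries, on a log axis, by group; each point is a library, and bars give the mean and SD of 6 libraries. On this scale Mbp stood at 625 ± 38.1 CPM in RES and 198 ± 13.6 in NS, and Malat1 at 944 ± 155 CPM in SA and 242 ± 14 in NS.

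The 4 comparisons share the 6 NS libraries, which alone makes their results alike. Genes higher against NS in both SA and SA:ANH IP numbered 1021, and lower in both 555, where independent lists would share 177 and 101. Simulated unchanged groups set against the same controls shared 0 and 0. With 3 NS libraries given to each comparison the shared calls were 623 and 287, against 82 and 44 for independent lists. The fold changes of that pair had a covariance over genes of 0.186, against 0.103 in the simulation. For SA and ANH it was 0.094, no higher than the 0.0999 simulated. For ANH and RES it was 0.132 against 0.0967, and the other 3 pairs lay between 0.124 and 0.128 with 0.093 to 0.106 simulated. For ANH and RES the shared calls were 113 and 138 (independent lists 11 and 15), and 40 and 40 with the controls split (independent lists 2 and 3). Across all 4 subtypes 38 genes were higher and 75 lower, where independent lists would share 0.12 and 0.094 and the simulation 0 and 0. Unchanged groups hardly have calls to share, so the 0 does not measure what the shared NS libraries add. Splitting the controls need not remove it either. The NS libraries may come from the same RNA source, whose traits would then sit in both parts.

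The subtypes were also set against each other in IP, which leaves the NS libraries out. Myelin genes separated RES and ANH from SA and SA:ANH. Mbp stood at -1.88 ± 0.05, adjusted p = 3.17e-24 in SA against RES, at -2.45 ± 0.05 in SA:ANH against RES and at -1.95 ± 0.05 in SA:ANH against ANH. Mobp stood at -2.84 ± 0.13 in SA:ANH against RES and -2.18 ± 0.13 against ANH. Of the oligodendrocyte markers in SA against RES, of 20 members 0 rose, 18 fell and 2 did not pass, and 0 rose and 20 fell adjusted over the list alone (median -2.55; camera adjusted p = 5.55e-40). Sst stood at -2.40 ± 0.08 in SA against RES, where also Zbtb20 (-3.20 ± 0.14) and the calcium sensor Hpca (-0.77 ± 0.03) were lower. Igfbp4, which binds insulin-like growth factors, was lower in SA:ANH (-1.11 ± 0.04) and ANH (-0.77 ± 0.04) than in RES, and Trbc2 was higher in SA:ANH than in RES (1.57 ± 0.08).

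Ap3b2 and Clasp2, both enriched by the pulldown, had their lowest IP group mean in ANH. Ap3b2 stood at -1.13 ± 0.04, adjusted p = 1.34e-21 in ANH against RES and at 1.55 ± 0.04, adjusted p = 6.37e-26 in SA against ANH and Clasp2 at -0.90 ± 0.04 and 1.32 ± 0.04. Necab2 was also lower in ANH than in RES (-0.76 ± 0.05). In SA:ANH against ANH, Ap3b2 stood at 0.76 ± 0.04 and Clasp2 at 0.70 ± 0.04. Meg3 and Snhg11 were higher in SA than in ANH (1.71 ± 0.05 and 1.74 ± 0.06). In SA:ANH against SA, Calb1 (1.36 ± 0.07), Hpca (0.71 ± 0.03) and Olfm1 (0.45 ± 0.02) were higher, and Ap3b2 (-0.78 ± 0.04) and Fezf2, a transcription factor of deep-layer projection neurons (-1.0 ± 0.05), lower. Layer 5 extratelencephalic markers were lower in SA:ANH than in SA: of 15 members 1 rose, 14 fell and 0 did not pass, with equal counts adjusted over the list alone (median -0.85; camera adjusted p = 1.4e-27). Upper layer markers were higher: of 15 members 7 rose, 2 fell and 6 did not pass, and 8 rose and 2 fell adjusted over the list alone (median 0.48; camera adjusted p = 8.55e-06). In SA against ANH the layer 5 list was higher, and of 15 members 11 rose, 1 fell and 3 did not pass, and 14 rose and 1 fell adjusted over the list alone (median 0.46; camera adjusted p = 1.31e-09).

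Ribosomal protein genes differed between subtypes as well. Against RES, 69 of 74 rose in SA and 74 in SA:ANH, with 71 and 74 adjusted over the list alone (camera adjusted p = 1.15e-41 and 1.62e-57). In ANH against RES of 74 members 0 rose, 62 fell and 12 did not pass, and 0 rose and 70 fell adjusted over the list alone (median -0.27; camera adjusted p = 2.8e-37, and adjusted p = 0.0581 with an estimated correlation). Of the 4 genes followed in every comparison, Bdnf stood at -0.14 ± 0.06, adjusted p = 0.1 in SA against ANH, 0.20 ± 0.06, adjusted p = 0.0329 in SA:ANH against SA and 0.24 ± 0.06, adjusted p = 0.00635 in SA:ANH against RES. Fos stood at -0.26 ± 0.11, adjusted p = 0.0972, -0.49 ± 0.11, adjusted p = 0.00309 and -0.27 ± 0.11, adjusted p = 0.115 in the same comparisons, Fkbp5 at -0.17 ± 0.14, adjusted p = 0.433, -0.09 ± 0.14, adjusted p = 0.789 and -0.57 ± 0.14, adjusted p = 0.00355, and Rpl10a at 0.03 ± 0.05, adjusted p = 0.704, 0.19 ± 0.05, adjusted p = 0.0136 and -0.17 ± 0.05, adjusted p = 0.026. Against RES, ANH stood at 0.18 ± 0.06, adjusted p = 0.0624 for Bdnf, 0.47 ± 0.11, adjusted p = 0.00507 for Fos, -0.31 ± 0.14, adjusted p = 0.171 for Fkbp5 and -0.39 ± 0.05, adjusted p = 2.71e-06 for Rpl10a, and SA at 0.04 ± 0.06, adjusted p = 0.782, 0.22 ± 0.11, adjusted p = 0.251, -0.48 ± 0.14, adjusted p = 0.0183 and -0.36 ± 0.05, adjusted p = 5.98e-06. SA:ANH against ANH gave 0.06 ± 0.06, adjusted p = 0.582 for Bdnf, -0.75 ± 0.11, adjusted p = 4.91e-06 for Fos, -0.26 ± 0.14, adjusted p = 0.218 for Fkbp5 and 0.23 ± 0.05, adjusted p = 0.00165 for Rpl10a. In a fit of only the 12 libraries compared, Bdnf and Rpl10a no longer passed in SA:ANH against SA, and Bdnf was also lost there with limma voom and without the low-count filter. DESeq2 called Bdnf in SA against ANH and in ANH against RES.

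The number of genes that differed was 3830 between SA and ANH (2135 higher in SA, 1695 lower), 2977 between SA:ANH and ANH (1805 and 1172), 2304 between SA:ANH and RES (1368 and 936), 1938 between SA and RES (1138 and 800), 1588 between SA:ANH and SA (815 and 773) and 1535 between ANH and RES (630 and 905). Processed pseudogenes made up 238 of the genes between SA and ANH, with 22 higher and 216 lower in SA. A test for any difference among the 5 IP groups called 5524 of 16670 genes, with Mbp (adjusted p = 1.12e-28), Ap3b2 (1.46e-24), Meg3 (3.2e-24) and Igfbp4 (1.57e-23) among the smallest values. In that test the adjusted p was 2.96e-06 for Bdnf, 5.24e-06 for Fos, 0.000162 for Fkbp5 and 9.65e-08 for Rpl10a.

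In the bulk tissue, red cell transcripts were higher in all 4 subtypes than in NS, and several transcripts known from fat tissue, and growth hormone, stood highest in NS. Hba-a1, an alpha-globin, stood at 628 ± 8.8 CPM in SA against 356 ± 7.9 in NS (0.82 ± 0.03, adjusted p = 5.1e-20; ENSMUSG00000069919.8, chromosome 11, 32233511 to 32234465), and rose by 0.88 ± 0.03 in SA:ANH, 0.85 ± 0.03 in ANH and 0.55 ± 0.03 in RES. Alas2, the red cell enzyme that starts heme synthesis, rose by 1.08 ± 0.15, 1.33 ± 0.16, 1.28 ± 0.15 and 1.0 ± 0.15. Of the blood cell list in SA, of 7 members 5 rose, 0 fell and 2 did not pass, with equal counts adjusted over the list alone (median 0.78; camera adjusted p = 4.91e-21). In SA:ANH, ANH and RES 4, 5 and 4 of 7 rose and 0 fell, with 5 in each adjusted over the list alone (camera adjusted p = 1.18e-14, 1.49e-13 and 4.32e-12).

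Ucp1, the uncoupling protein of brown fat, held 17.2 ± 1.74 CPM in NS Input (ENSMUSG00000031710.5, chromosome 8, 84016981 to 84025081) and 0 counts in SA and SA:ANH Input, at least 845-fold and at least 767-fold lower with a floor of 3 counts over the group. In ANH and RES it held 5 and 1 counts, a ratio of NS to the group of 493 (211 to 1520) and 2570 (460 to 101000), with 95% intervals in parentheses that cover counting error only. Fabp4, a fatty acid carrier of fat cells (ENSMUSG00000062515.4, chromosome 3, 10269148 to 10273636), gave ratios of 380 (212 to 761), 758 (324 to 2340), 677 (311 to 1850) and 2110 (584 to 17400) in SA, SA:ANH, ANH and RES. The carbonic anhydrase Car3 gave 173 (105 to 309), 53.5 (39.7 to 73.8), 70.1 (50.5 to 100) and 109 (73.3 to 171). Gh, growth hormone (ENSMUSG00000020713.7, chromosome 11, 106191097 to 106192691), stood at 44.6 ± 2.81 CPM in NS and 6.74 ± 1.23 in SA:ANH, a ratio of 6.53 (6.09 to 7.01). It gave 172 (125 to 243) in SA and 636 (346 to 1330) in ANH, and with 0 counts in RES was at least 2210-fold lower there. Prl and Pomc, also pituitary transcripts, were chosen after their values were seen. Prl went with Gh: it was at least 230-fold lower in SA and at least 224-fold lower in ANH, each at 0 counts, and the ratio of NS to the group was 6.03 (4.9 to 7.49) in SA:ANH and 699 (125 to 27700) in RES. Pomc differed less, with ratios of NS to the group of 1.06 (0.96 to 1.16) in SA, 1.17 (1.06 to 1.29) in SA:ANH, 1.37 (1.24 to 1.52) in ANH and 1.09 (0.988 to 1.2) in RES. Of the fat genes with at least 294 counts in each other Input group, Agpat2 stood at -2.09 ± 0.21, -2.32 ± 0.22, -2.16 ± 0.21 and -1.79 ± 0.21, Cidea at -1.74 ± 0.12, -1.56 ± 0.12, -1.72 ± 0.12 and -1.84 ± 0.12, Thrsp at -1.40 ± 0.09, -1.33 ± 0.09, -1.36 ± 0.09 and -1.45 ± 0.09, and the desaturase Scd1 at -1.25 ± 0.08, -1.21 ± 0.08, -1.02 ± 0.08 and -1.24 ± 0.08. Set against RES in place of NS, a comparison chosen after the data were seen, the same Input libraries gave 200 genes in SA, 126 in SA:ANH and 766 in ANH, of which 55, 47 and 131 had been called against NS.

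**Figure D3:**
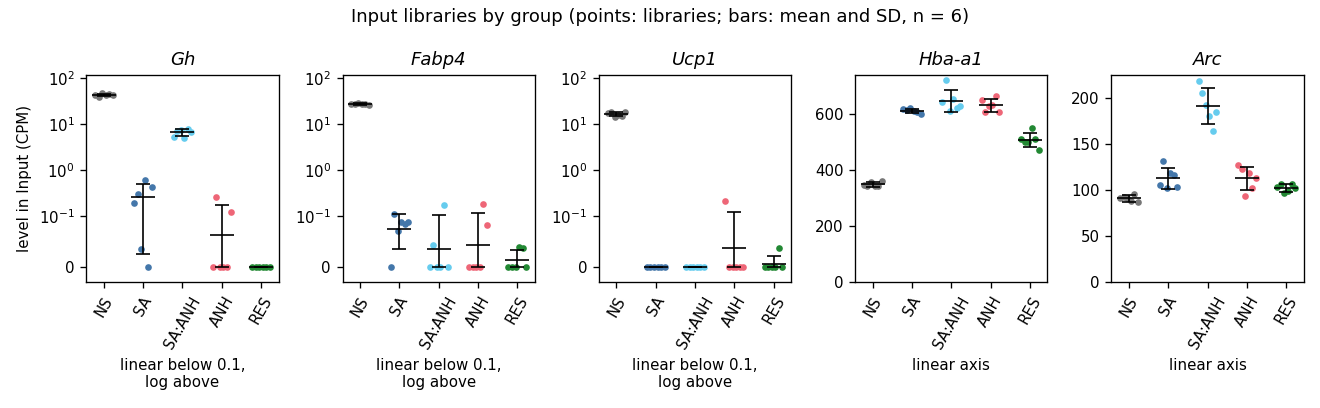
Levels of Gh, Fabp4, Ucp1, Hba-a1 and Arc in the 30 Input libraries, in CPM scaled over all 60 libraries, by group; each point is a library, and bars give the mean and SD of 6 libraries, with lower ends stopping at 0. The axes of Gh, Fabp4 and Ucp1 are linear below 0.1 and logarithmic above, and those of Hba-a1 and Arc are linear from 0; on this scale Gh stood at 43.7 ± 2.84 CPM in NS, and Hba-a1 at 348 ± 8.23 in NS and 610 ± 6.72 in SA.

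Myelin genes were higher than in NS in Input as well, mainly in ANH and RES. In ANH Input 16 of 20 members rose, 0 fell and 4 did not pass, and 19 rose and 0 fell adjusted over the list alone (median 0.66; camera adjusted p = 1.32e-54). Mbp rose by 0.75 ± 0.02, adjusted p = 1.88e-26, Mobp by 0.83 ± 0.05, Mog by 0.80 ± 0.07 and Hapln2, a matrix protein of nodes of Ranvier, by 1.05 ± 0.15. In RES Input of 20 members 13 rose, 0 fell and 7 did not pass, and 17 rose and 0 fell adjusted over the list alone (median 0.44; camera adjusted p = 9.93e-37). Mbp stood at 0.53 ± 0.02, Mog at 0.75 ± 0.07 and Opalin at 0.69 ± 0.06. In SA Input of 20 members 9 rose, 0 fell and 11 did not pass, and 13 rose and 0 fell adjusted over the list alone (median 0.21; camera adjusted p = 7.21e-17). Mbp stood at 0.31 ± 0.02. In SA:ANH Input of 20 members 4 rose, 0 fell and 16 did not pass, and 7 rose and 1 fell adjusted over the list alone (median 0.11; camera adjusted p = 0.00131, and adjusted p = 0.0504 with an estimated correlation). Mbp stood at 0.11 ± 0.02.

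SA Input also had lower Gfap, the intermediate filament of astrocytes (-0.75 ± 0.05, adjusted p = 4.17e-13), and lower Gria2 (-0.32 ± 0.04) and Lyz2, the lysozyme of macrophages (-0.92 ± 0.12). For chaperones, of 28 members 0 rose, 6 fell and 22 did not pass, and 0 rose and 10 fell adjusted over the list alone (median -0.10; camera adjusted p = 1.42e-06). The endoplasmic reticulum chaperone Hsp90b1 stood at -0.26 ± 0.04. For immediate early genes, of 29 members 7 rose, 1 fell and 21 did not pass, and 11 rose and 1 fell adjusted over the list alone (median 0.15; camera adjusted p = 0.000183). Bdnf stood at -0.36 ± 0.09, adjusted p = 0.0267, and was not called without the low-count filter or in a fit of the 12 libraries compared. Fos (0.33 ± 0.11, adjusted p = 0.083), Rpl10a (-0.07 ± 0.07, adjusted p = 0.74) and Fkbp5 (-0.09 ± 0.09, adjusted p = 0.766) did not pass, although DESeq2 called Fos. SA and NS Input differed in 515 of 18170 genes, 224 higher and 291 lower. DESeq2 called 808.

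In SA:ANH Input, immediate early genes were higher than in NS, opposite to their direction in IP. Arc, a synaptic activity gene, stood at 194 ± 18 CPM against 93.1 ± 3.31 (1.06 ± 0.06, adjusted p = 1.65e-14; ENSMUSG00000022602.15, chromosome 15, 74540932 to 74544419), Fos at 43.8 ± 6.08 against 22.4 ± 3.87 (0.97 ± 0.11, adjusted p = 4.66e-08), Npas4 at 1.03 ± 0.12, the phosphatase Dusp1 at 0.77 ± 0.06 and Junb at 0.67 ± 0.05. Of the list, of 29 members 11 rose, 3 fell and 15 did not pass, and 12 rose and 4 fell adjusted over the list alone (median 0.23; camera adjusted p = 1.23e-08). The clock output gene Dbp rose by 0.68 ± 0.05 and Ciart, a circadian repressor, by 0.70 ± 0.08. For mitochondrially encoded genes, of 15 members 0 rose, 9 fell and 6 did not pass, and 0 rose and 13 fell adjusted over the list alone (median -0.34; camera adjusted p = 2.12e-10, and adjusted p = 0.161 with an estimated correlation). For ribosomal protein genes, of 74 members 13 rose, 0 fell and 61 did not pass, and 17 rose and 0 fell adjusted over the list alone (median 0.04; camera adjusted p = 5.69e-05, and adjusted p = 0.48 with an estimated correlation). Rpl10a stood at 0.22 ± 0.07, adjusted p = 0.0349, with replicate 2 at 116 CPM and the others between 81.1 and 89.9, and was not called in a fit of the 12 libraries compared, with pseudogenes left out or without replicates 1 and 2. Bdnf (-0.27 ± 0.09, adjusted p = 0.0895) and Fkbp5 (-0.12 ± 0.09, adjusted p = 0.55) did not pass.

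Processed pseudogenes made up 270 of the 1026 genes, of 18170, that differed between SA:ANH and NS Input (462 higher, 564 lower), and 269 of them were lower. They held 1.36% ± 0.1 of counts in SA:ANH Input and 1.62% ± 0.083 in NS Input, and such copies share reads with their parent genes. The count was 563 with pseudogenes left out and 207 without SA:ANH replicates 1 and 2, both chosen after the data were seen. Leaving out any of the 14 other pairs of SA:ANH libraries gave 336 to 1155. Without the 2 libraries 199 of the first calls remained.

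In ANH Input, beside the myelin genes, layer 6 corticothalamic markers were higher: of 17 members 3 rose, 0 fell and 14 did not pass, and 5 rose and 0 fell adjusted over the list alone (median 0.15; camera adjusted p = 0.00537). Cplx3 stood at 0.54 ± 0.08. The kinase gene Prkcd stood at -0.93 ± 0.13. Rpl10a rose by 0.26 ± 0.06, adjusted p = 0.0199. Bdnf (-0.12 ± 0.09, adjusted p = 0.584), Fos (0.09 ± 0.11, adjusted p = 0.762) and Fkbp5 (0.07 ± 0.09, adjusted p = 0.795) did not pass. ANH and NS Input differed in 476 genes, 285 higher and 191 lower. DESeq2 called 728.

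RES Input had less Ptgds, the prostaglandin D synthase of the leptomeninges and oligodendrocytes (340 ± 22.2 against 651 ± 22.8 CPM; -0.94 ± 0.03, adjusted p = 5.79e-22; ENSMUSG00000015090.14, chromosome 2, 25356721 to 25360058). Meningeal and fibroblast markers were lower with it: of 14 members 0 rose, 5 fell and 9 did not pass, and 0 rose and 8 fell adjusted over the list alone (median -0.59; camera adjusted p = 1.36e-10). Dbp rose by 0.80 ± 0.05 and Ciart by 0.83 ± 0.08, and Prkcd stood at -1.16 ± 0.13. For chaperones, of 28 members 0 rose, 7 fell and 21 did not pass, and 0 rose and 10 fell adjusted over the list alone (median -0.11; camera adjusted p = 3.85e-06). For mitochondrially encoded genes, of 15 members 0 rose, 8 fell and 7 did not pass, and 0 rose and 13 fell adjusted over the list alone (median -0.31; camera adjusted p = 1.59e-10, and adjusted p = 0.176 with an estimated correlation). Their share of counts was 1.63% ± 0.075 in RES and 1.95% ± 0.105 in NS Input. Bdnf stood at -0.41 ± 0.09, adjusted p = 0.0086. Fos (0.31 ± 0.11, adjusted p = 0.1), Rpl10a (0.07 ± 0.07, adjusted p = 0.637) and Fkbp5 (0.03 ± 0.09, adjusted p = 0.922) did not pass. RES and NS Input differed in 587 genes, 356 higher and 231 lower. DESeq2 called 902.

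A test for any difference among the 5 Input groups called 2343 of 18170 genes, with Mbp (adjusted p = 1.29e-26), Fabp4 (7.88e-26), Ptgds (1.46e-22), Gh (2.07e-21) and Hba-a1 (2.27e-21) at the smallest values. In it the adjusted p was 0.00826 for Bdnf, 4.23e-08 for Fos, 0.47 for Fkbp5 and 0.00119 for Rpl10a.

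Whether the differences from NS themselves differed between IP and Input was tested in a model of all 60 libraries. Mbp and Sst had the smallest p. Mbp (adjusted p = 5.57e-39) stood at 1.15 in ANH IP and 0.75 in ANH Input, at 1.66 and 0.53 in RES, and at -0.79 and 0.11 in SA:ANH. Sst (2.81e-35) stood at 1.49 in RES IP and -0.04 in RES Input, which did not pass. Ap3b2 (1.31e-30) and Trf (1.89e-30) were also among the smallest. Ap3b2 stood at 0.65 in SA IP and -0.90 in ANH IP, and between -0.08 and 0.05 in Input, where it passed in no subtype. The effect differed for 4667 of 18937 genes. For Bdnf the adjusted p of this test was 0.71, for Fos 1.74e-13, for Fkbp5 0.00706 and for Rpl10a 1.04e-05.

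**Figure D4:**
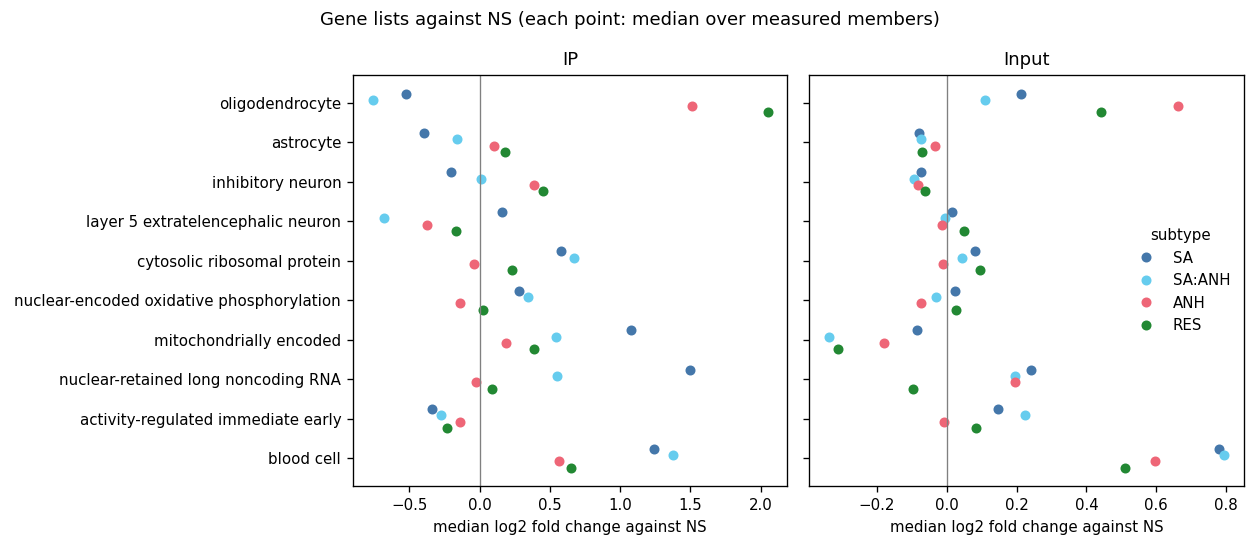
Median log2 fold change against NS (horizontal axis) of 10 gene lists (rows) in each of the 4 subtypes (colours), in IP on the left and Input on the right, on axes of different range, from 6 libraries per group. Oligodendrocyte markers have a median of 2.05 in RES IP and 1.51 in ANH IP, and ribosomal protein genes 0.58 in SA IP and 0.67 in SA:ANH IP.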

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

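The test of a difference between fractions, the tests on fat and pituitary markers not looked at before and the random splits of libraries were fixed before their results were seen, and the other tests in this part were chosen only afterwards.

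A single library stood far from the other 5 of its group in 8 of 154 sets of 6 values examined, and chance gives about 1 in 20. Rpl10a was at 116 CPM in SA:ANH Input replicate 2, with the others between 81.1 and 89.9. Fos was at 38.2 CPM in ANH IP replicate 2 (others 24.8 to 29.4), and Fkbp5 at 25.5 CPM in SA IP replicate 4 (others 15 to 18). Bdnf was low in SA IP replicate 1, at 63.4 CPM (others 69.4 to 72.3), and in NS IP replicate 3, at 78.6 CPM (others 91.1 to 96.9). SA:ANH IP replicate 6 had both the highest Malat1 of its group, 776 CPM (others 398 to 510), and the highest mitochondrially encoded share, 0.04679% of counts (others 0.02407% to 0.03115%). Malat1 was highest in replicate 6 in the other IP groups as well, at 1215 CPM in SA, 300.2 in ANH, 353.2 in RES and 267.5 in NS. In ANH IP replicate 3, 20614 genes were detected, against 19602 to 19852 in the others.

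The difference from NS was itself unlike in IP and Input for 4667 genes, by the test of that difference in a model of all 60 libraries (edgeR, Benjamini-Hochberg adjusted). Among the smallest adjusted p were those of Mbp (5.57e-39), Sst (2.81e-35), Ap3b2 (1.31e-30) and Trf (1.89e-30).

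The 6 libraries of a group lay close together. The sum of 12 fat genes, which could vary widely between separate animals if it came from tissue taken along, had a coefficient of variation of 3.92% over the 6 NS Input libraries. That is what libraries made from one RNA source would show, and the labels do not say whether they were. A library deposited more than once is argued against, because the closest pair of libraries within any group differed by 7.56 times sampling noise (scaled chi-square over genes). No biological explanation was tested.

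Several transcripts of fat and pituitary stood high in NS Input, where 12 fat genes summed to 329 ± 13 CPM (SD, n = 6) against group means of 91 to 104 in the other Input groups. Of 13 fat markers not looked at before, 10 had their highest Input group mean in NS (exact one-sided binomial p = 1.61e-05 against a chance of 20%). RNA of fat in these libraries would give this, but the list does not tell brown fat from other fat. That p treats genes of the same 6 libraries as independent and counts near-ties in full, so it does not measure support for a source. In other groups 6 of the 13 also reached 1 CPM. The markers ran from Plin1 at 2.24 CPM against 0.0101 in the other groups to Lipe at 6.03 against 5.51. Dio2 stood at 8.71 against 9.13 and Dgat2, the most abundant, at 108 against 111. Of 8 pituitary markers 4 had their highest Input group mean in NS (exact one-sided binomial p = 0.0563, with the same limit), which leaves pituitary RNA open. Among them Cga stood at 1.44 CPM against 0.0055, and 1 of the 8 reached 1 CPM elsewhere. Reads shared evenly among all libraries are argued against for 8 of the 12 fat genes, those under 1 CPM in every other group. They summed to 93.6 ± 4.4 CPM in NS Input and to at most 2.23 CPM in any of the 54 other libraries, a ratio of 41.9. These 8 were picked for low values elsewhere, but even sharing would have raised them to the NS level there too. All 12 together summed in NS Input to 2.96 times the highest of the 54 other libraries, which decides nothing. A difference between NS mice and the others cannot be told apart from a difference in the RNA. Group and source are the same 6 libraries. The 12 genes summed to 17.1 ± 3.1 CPM in NS IP and to group means of 10.6 to 16 in the other IP groups. Bulk Input has no step that would remove such RNA. Gh was not confined to NS Input: it stood at 3.03 ± 0.829 CPM in NS IP and at group means of 0 to 0.333 in the other IP groups. In IP too, Gh was called lower than in NS in all 4 subtypes.

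Oligodendrocyte markers stood higher in ANH and RES IP, although the pulldown removes most of their RNA. More carry-over of every other cell type is argued against as the whole cause, because the median change of oligodendrocyte markers lay 1.41 above that of astrocyte markers in ANH IP (quartiles 0.96 to 1.82 against -0.05 to 0.31) and 1.87 above it in RES IP (1.59 to 2.56 against -0.09 to 0.35); inhibitory neuron markers, which the pulldown also depletes, rose as a list but by less, with quartiles of -0.33 to 0.64 in ANH and 0.15 to 0.74 in RES, and Sst at 1.03 and 1.49, so some carry-over is left open. More oligodendrocytes in the tissue, carried over at a fixed share, are argued against as the whole cause, because the members' change in IP exceeded that in Input by a median of 0.79 in ANH (quartiles 0.36 to 1.14; 17 of 20 members) and 1.62 in RES (1.09 to 2; 20 of 20). With both together, the difference between the oligodendrocyte and astrocyte lists in IP would match that in Input. It was 1.36 higher in RES, where the inhibitory neuron list's excess had quartiles of only 0.27 to 0.84. In ANH it was 0.71 higher. Both together stay open in ANH, since the quartiles of inhibitory neurons, -0.33 to 0.67, overlap those of oligodendrocytes. All these comparisons of lists take their RNA in IP to be carry-over alone. RNA of the tagged cells was not told apart from it, and no other cell types were compared, so the arguments hold only under that assumption. A difference between the subtypes stays open: 18 of 20 members passed the test of a difference between fractions, and a carry-over of oligodendrocyte RNA alone was not tested and cannot be told apart from it, since subtype and library source are the same 6 libraries.

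For each of the 18 results 1 of 25 splits, the real one, called as many genes as the real one. With 25 splits no share under 1 in 25 could be seen. Chance in the grouping of these libraries is therefore argued against but not excluded. Each result is read at 1 in 25 with no correction over the 18, and splits of libraries say nothing of chance differences between RNA sources. The real value and the highest of the other splits were 14280 and 1 for IP against Input. Against NS in IP they were 2766 and 423 in SA, 3288 and 943 in SA:ANH, 1233 and 52 in ANH, and 727 and 9 in RES. Against NS in Input they were 515 and 11 in SA, 1026 and 73 in SA:ANH, 476 and 86 in ANH, and 587 and 14 in RES. Between subtypes in IP they were 1938 and 536 for SA and RES, 2304 and 1 for SA:ANH and RES, 1535 and 25 for ANH and RES, 1588 and 262 for SA:ANH and SA, 2977 and 1176 for SA:ANH and ANH, and 3830 and 1428 for SA and ANH. They were 5524 and 0 for any difference in IP, 2343 and 9 for any difference in Input, and 4667 and 232 for the difference between fractions.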

How the results depend on the processing

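The comparisons with pseudogenes left out, with named libraries left out, with RES in place of NS and with the oligodendrocyte covariate were chosen only after the data were seen, and the others were fixed in advance.

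Of the counts of genes under the alternatives fixed in advance, 101 stayed within 1.5 times the reported count and 3 did not, and no gene called in the reported fits was called with the other sign. Under DESeq2 the Input counts moved to 808 in SA, 728 in ANH and 902 in RES, with 491, 458 and 556 of the reported calls kept; the cause was not tested. Of the values of single genes named, 1765 kept their side of the threshold under these alternatives, 7 fell short of it and 3 newly passed, and none turned round. RLE factors moved the median of all genes by at most 0.045 and the share of higher calls by at most 8.4 points (DESeq2 8.7). Of the list calls, 56 no longer passed with an estimated correlation; with fry, which does not compare a list with other genes, 5 no longer passed and 101 newly passed.

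Replicate numbers run from 1 to 6 in every group, and the check of their deviations gave a weak link between libraries of equal number. The labels do not say that equal numbers share a source. Over 30 pairs of IP and Input libraries of 1 number the correlation ran from -0.03 to 0.18, with 7 over 0.1, and 12 of 30 IP libraries correlated best with the Input library of their own number, where chance gives 5, a hint from the data and not the design. Across groups it ran from -0.08 to 0.15 in IP and from -0.16 to 0.21 in Input. With the number as a block the counts were 2855, 3387, 1369 and 775 for SA, SA:ANH, ANH and RES against NS in IP, and 599, 1226, 599 and 763 in Input. In the fit of both fractions the block instead paired the IP and Input libraries of equal group and number, which the labels do not give. The counts were then 14229 for IP against Input and 4274 for the difference between fractions. In camera with the block, 6 list calls no longer passed and 3 newly passed.

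Leaving out processed pseudogenes, which removes genes that had been called, gave 563 genes in SA:ANH Input (551 of the reported calls kept), and leaving out SA:ANH Input replicates 1 and 2 gave 207 (199 kept). The other 14 pairs of its libraries gave 336 to 1155, with a median of 535.5. Without SA:ANH IP replicate 6 the count stayed within 1.5 times.

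With RES in place of NS, the Input counts were 200 in SA (55 kept, 16 with the other sign), 126 in SA:ANH (47 and 8) and 766 in ANH (131 and 4). The following changed sign, and the cause was not tested beyond the change of reference. In SA against RES, Gh stood at 5.66, Cidea at 0.09, Thrsp at 0.05, Bdnf at 0.05, Mbp at -0.22, Dbp at -0.38, Il33 at -0.03 and Kcnh4 at -0.14. In SA:ANH, Gh stood at 10.32, Cidea at 0.28, Thrsp at 0.12, Scd1 at 0.04, Lyz2 at 0.06, Mbp at -0.42, Ciart at -0.13, Dbp at -0.12 and Kcnh4 at -0.14. In ANH, Cidea stood at 0.12, Thrsp at 0.09, Scd1 at 0.22, Prkcd at 0.23, Lyz2 at 0.18, Dbp at -0.55 and Kcnh4 at -0.07. The values of Gh are fitted against 0 counts in RES and are no bound.

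With the oligodendrocyte covariate, the IP counts were 609 in SA (588 kept), 815 in SA:ANH (789), 9 in ANH (9) and 2 in RES (2). Trf turned to -0.04 and Gfap to -0.59 in ANH, and Mog to -0.01 and Gfap to -1.2 in RES. The covariate varies mainly between groups, with 98.3% of its variance there, so by construction it takes group differences with it. What depth alone limits was not measured. On simulated data for SA against NS in IP, over 16670 genes, 18% of genes changed 1.2-fold were recovered. The changed genes there were drawn without those of low mean count.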

Other observations

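The genes named in this part were chosen only after their values were seen; the gene lists were fixed in advance.

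In IP, 38 genes were higher and 75 lower than in NS in all 4 subtypes, and simulated unchanged groups shared 0 and 0. The shared NS libraries add to such an overlap by an amount that was not measured, since unchanged groups hardly have calls to share. Rbm3, an RNA-binding protein induced by cold, rose by 0.66 ± 0.09 in SA, 0.95 ± 0.09 in SA:ANH, 0.54 ± 0.09 in ANH and 0.90 ± 0.09 in RES, and its relative Cirbp by 0.39 ± 0.05, 0.50 ± 0.05, 0.21 ± 0.05 and 0.58 ± 0.05. Dbp, a clock output gene, rose by 0.42 ± 0.05, 0.90 ± 0.05, 0.38 ± 0.05 and 0.68 ± 0.05. Nos1, the neuronal nitric oxide synthase, stood at -0.65 ± 0.08, -0.65 ± 0.08, -0.48 ± 0.08 and -0.51 ± 0.08, and Inhba at -0.95 ± 0.10, -0.58 ± 0.10, -0.54 ± 0.10 and -0.55 ± 0.10. Each of these values passed edgeR's test after Benjamini-Hochberg adjustment.

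In Input, 32 genes were higher and 38 lower in all 4 subtypes, with 0 and 0 in the simulation. Many of the 38 are fat, pituitary and immunoglobulin transcripts that stood high in NS Input, such as Ucp1, Fabp4, Gh, Prl and Igkc. Dbp was again among the higher genes, at 0.41 ± 0.05, 0.68 ± 0.05, 0.24 ± 0.05 and 0.80 ± 0.05 in SA, SA:ANH, ANH and RES. Il33, an alarmin made by glia, rose by 0.46 ± 0.11, 0.58 ± 0.11, 0.65 ± 0.11 and 0.49 ± 0.11, and the potassium channel gene Kcnh4 by 1.06 ± 0.20, 1.06 ± 0.21, 1.14 ± 0.20 and 1.2 ± 0.20. Lyz2 stood at -0.92 ± 0.12, -0.83 ± 0.12, -0.71 ± 0.12 and -0.89 ± 0.12. Meningeal and fibroblast markers were lower in the other subtypes as well as in RES: of 14 members 0 rose, 1 fell and 13 did not pass, and 0 rose and 5 fell adjusted over the list alone (median -0.33; camera adjusted p = 3.36e-05) in SA, and in SA:ANH and ANH 0 of 14 passed one by one (medians -0.28 and -0.2; camera adjusted p = 0.00406 and 0.0104). In RES IP, interferon and inflammatory genes were higher: of 16 members 2 rose, 0 fell and 14 did not pass, and 5 rose and 0 fell adjusted over the list alone (median 0.19, camera adjusted p = 0.00528). This was not particular to RES for each member. Ifit3 was higher in IP in all 4 subtypes, by 1.39 in SA, 1.04 in SA:ANH, 1.09 in ANH and 1.2 in RES. In SA IP Ifi27 (0.48 ± 0.15) and Nfkbia (0.34 ± 0.10) also rose, and Serpina3n fell (-0.36 ± 0.10).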
